A study of Mus musculus with 6 samples.

How the data were processed

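Total RNA had been extracted with Trizol from liver tumours of 6 male mice, and biotin-labelled cRNA had been made from 5 µg of it and hybridized to Affymetrix mouse arrays, per the labels' protocols. The submitters' processing notes name RMA, which corrects the background, quantile-normalizes the arrays and summarizes probes into probe sets. No version is stated there. The deposited values are therefore log2 expression levels, made by the authors. The array medians differed by at most 0.0289 log2. RMA assumes that most genes do not differ between arrays, so a shift shared by most genes would not be visible. The scanner files were not used here. The labels record the CD-1 background strain for the mice and embryos from B6CBAF1/J matings for the transgene injection.

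The table held 22690 probe sets. The 64 Affymetrix control probe sets were left out, which left 22626. Gene names came from the platform annotation, with symbols updated through gene IDs against a RefSeq gene table of the assembly GRCm38.p6. Of the probe sets tested, 20380 had 1 gene symbol, 691 had several and 1555 had none; 20351 of the 20380 gene IDs were in the gene table. No gene was named from a probe set with several symbols. The 2981 probe sets whose type marks possible binding to related transcripts (x_at or s_at) were kept and are pointed out where named. For gene-level work each of 12393 genes was represented by its probe set with the highest mean over all 6 arrays. Coordinates are not given, since no file states a build.

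Groups were taken from the genotype labels. Replicates were numbered in accession order, and the titles give each array its own animal number, so the samples were treated as separate animals. Pairs of arrays correlated with Pearson's r between 0.987 and 0.993 over probe sets (a description of array pairs, with probe sets not independent), and no 2 arrays were identical. The animal numbers fall into a lower and a higher range. The labels do not say that these mark a batch, but before the data were examined the range was set down as a possible block and fitted as an alternative.

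Differences (Alb/AEG-1 minus wild type) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, 7.53 total degrees of freedom), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. A second count used an unadjusted p below 0.05 and a difference of at least 1.5-fold. Single list means can reach no exact permutation p below 0.1 with 3 against 3 arrays, so they are given without one. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

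Gene lists were fixed before the data were examined: 45 lists with 1035 listed members, 125 of which have no probe set named here and are not analysed. They cover pathways of liver and cancer and markers of other cell types. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 45 lists, and members were also adjusted over the list alone. With an estimated correlation 0 lists passed, and 0 by fry, so camera's calls rest on the preset value. In 4 lists the mean and the direction of the test had opposite signs, as stated at each.

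The rule for genes named in the text was also fixed beforehand. It took up to 15 genes per direction with a called probe set and separated groups, filled up to 10 by the smallest unadjusted p where fewer passed, then Mtdh and F12, then the 4 members of each list with the smallest unadjusted p. Golm1, Ly6d, Gpc3, Mttp, Mki67, Cyp2c37 and the genes of the animal number ranges were chosen after their values were seen.

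The fit was checked on 10 simulated data sets with the arrays' own spread, in which 200 of 22626 probe sets were changed. It called 87.2% of probe sets changed 2-fold and 98.6% of those changed 4-fold, and 5.4% of its calls were unchanged probe sets. Camera called a list of 25 genes shifted by 0.5 log2 in 10 of 10 data sets and 0 unshifted lists. These simulations had no correlation between genes. Spreads were drawn at random from the fitted distribution, with no link to which probe sets changed and no animal number ranges. In the data several genes with large differences also had a wide spread, and the Scd2 probe set with the highest mean did not pass at 10.3-fold. The shares above therefore do not give the power in the data.

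Alternatives were trend or robust moderation, quantile normalization, median centring, leaving out dim or cross-binding probe sets, 1 probe set or the mean of all probe sets per gene, array weights, the animal number range as a term, each array left out in turn, and for lists an estimated correlation, ranks and fry. The values were already log2, so the alternative for linear values was not needed. The combination of the animal number range with an estimated correlation was added after seeing the data. All 10 splits of the 6 arrays into 3 and 3 were also fitted.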

Results

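Liver tumours of 6 male mice were profiled, each on its own Affymetrix expression array. The tumours followed a single dose of the hepatocarcinogen N-nitrosodiethylamine (DEN), which forms mutagenic DNA adducts in hepatocytes after metabolism by cytochrome P450. It was injected at 10 µg per g body weight at 14 days of age, and tumours were taken at 28 weeks. The arrays fell into 2 groups of 3: tumours of wild-type mice, and tumours of Alb/AEG-1 mice carrying a transgene for astrocyte elevated gene-1 (AEG-1, the product of the gene Mtdh), microinjected as a 5.3-kb DNA fragment. The comparison asks which genes differ between tumours that arose with and without the transgene. Each value is a log2 expression level on the deposited scale. The lowest and highest values on the array of wild-type replicate 1 were 2.22 and 14.86. With 3 arrays per group, their number limits the precision. The labels give each array a different animal number, and the numbers form a lower range (wild-type replicate 1 and Alb/AEG-1 replicates 1 and 2) and a higher range (wild-type replicates 2 and 3 and Alb/AEG-1 replicate 3).

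Mtdh and the genes reported as partners or targets of AEG-1 showed no difference past the threshold. Mtdh, whose product is a scaffold protein of RNA-binding and signalling complexes, was at 9.17 ± 0.15 (SD, n = 3) in wild-type and 9.37 ± 0.21 in Alb/AEG-1 tumours, a difference of 0.20 ± 0.13 log2 (SE, adjusted p = 0.677). It was 0.11 with the animal number range as a term, 0.10 without Alb/AEG-1 replicate 1, 0.13 without wild-type replicate 2 and 0.31 without Alb/AEG-1 replicate 3. Of its 6 probe sets, 4 differed in that direction, by at most 0.20. The labels do not state the species or the untranslated regions of the transgene, so these probe sets do not check the genotype. F12, which encodes coagulation factor XII and is a reported target, differed by 0.15 ± 0.27 log2 (adjusted p = 0.877), with a wild-type SD of 0.63. Its difference was -0.18 without wild-type replicate 3 and 0.44 without wild-type replicate 2. Snd1, encoding a nuclease that binds AEG-1, differed by 0.14 ± 0.09 (0.09 without Alb/AEG-1 replicate 3) and Zbtb16, a transcriptional repressor, by -0.26 ± 0.12 (-0.17 without wild-type replicate 1). Over the 12 measured members of this list the mean difference was -0.02 (limma's camera, adjusted p = 0.819), and 0 members passed when adjusted over all probe sets or adjusted over the list alone.

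The clearest single difference was in Gbp7, an interferon-inducible guanylate-binding protein. One Gbp7 probe set rose from 5.10 ± 0.19 (SD, n = 3) to 6.84 ± 0.18, a difference of 1.74 ± 0.13 log2 (SE, 3.33-fold, adjusted p = 0.0391), and every Alb/AEG-1 value lay above every wild-type value. The other Gbp7 probe set differed by 1.18 ± 0.14 (adjusted p = 0.158). Several genes had larger differences with a wider spread that did not pass over all probe sets. Scd2, a stearoyl-CoA desaturase, differed by 3.37 ± 0.32 log2 (10.3-fold, adjusted p = 0.0748), and the tetraspanin Tspan8 by 4.90 ± 0.61 (adjusted p = 0.158, with no fold given since its wild-type values lie low on the scale). Dimmer Scd2 probe sets, with wild-type means of 3.86 and 3.51, differed less. Their differences were 1.05 ± 0.16 (limma, adjusted p = 0.33) and 0.53 ± 0.30 (adjusted p = 0.655, with overlapping groups).

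Among 22626 probe sets tested with limma, Gbp7 was the 1 past an adjusted p of 0.05, with 1 higher and 0 lower. At an unadjusted p below 0.05 there were 1823 probe sets, and 183 of these differed at least 1.5-fold, 155 of them higher and 28 lower in Alb/AEG-1 tumours. The 3 arrays of a group lay entirely beyond those of the other in 3319 probe sets (14.7%, where chance gives 10%). The Gbp7 call was lost with the animal number range as a term (difference 1.75 ± 0.15, adjusted p = 0.0803; 2.01 within the lower and 1.49 within the higher numbers) and without any 1 of the 6 arrays, with differences between 1.63 and 1.82 and adjusted p between 0.0692 and 0.14.

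The next named genes by p did not pass over all probe sets and are given as values. Those higher in Alb/AEG-1 tumours included Apoa4, an apolipoprotein of triglyceride-rich particles (1.51 ± 0.23 log2, adjusted p = 0.312; a probe set that may also bind related transcripts, with 1.94 in the other probe set), Akr1c18, a hydroxysteroid dehydrogenase (2.06 ± 0.32), and Anxa2, a calcium-dependent membrane-binding protein (1.13 ± 0.18, the same direction in 2 of 3 probe sets). Ifi27l2b, related to interferon-induced genes, differed by 1.34 ± 0.23 on a probe set that may bind its relatives, the receptor gene Tlr1 by 0.95 ± 0.16 and Tinag by 0.63 ± 0.08. Among named genes in the other direction, Iah1, an ester hydrolase, differed by -0.79 ± 0.11 (adjusted p = 0.283, a probe set that may bind related transcripts), Loxl1, a lysyl oxidase-like enzyme of elastic fibres, by -0.50 ± 0.10, and the growth factor gene Bmp2 by -0.36 ± 0.08. Rilpl1, Tspan2 and Sspo differed by -0.48 each, Htr1d by -0.44, Cep152 by -0.43 and Afg1l by -0.41. Only 1 of 2 Rilpl1 and 1 of 3 Tspan2 probe sets differed in that direction. One probe set with no gene symbol in the platform annotation used here differed by -2.97 ± 0.26 (adjusted p = 0.0616).

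**Figure D1:**
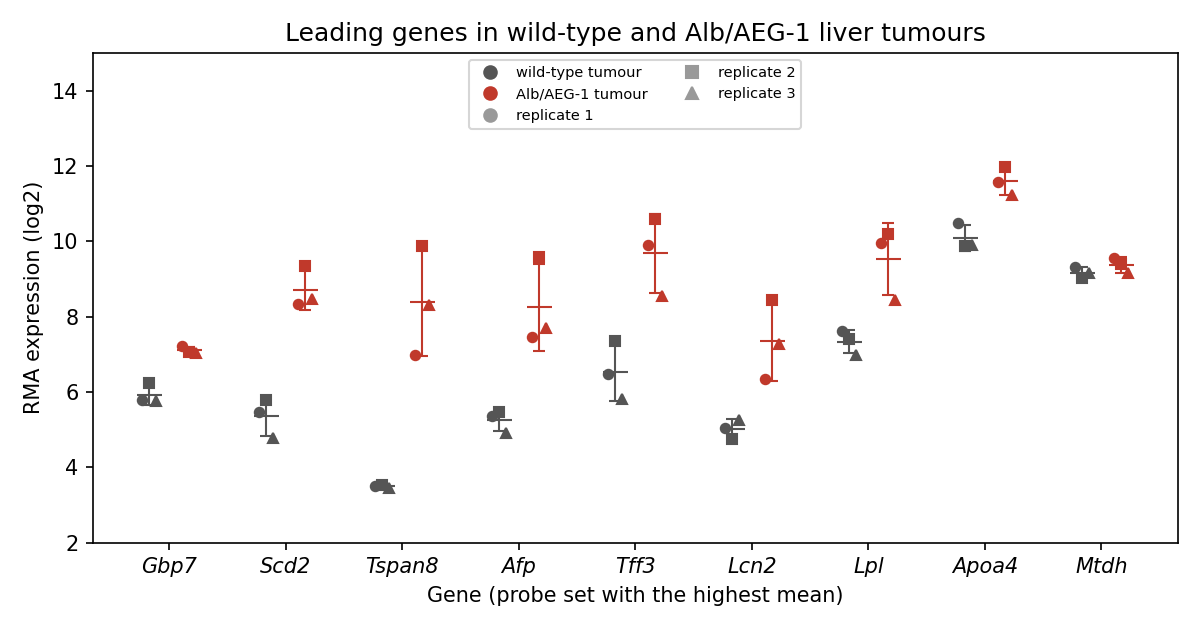
Expression (RMA log2, y axis) of 9 genes in 3 wild-type (grey) and 3 Alb/AEG-1 tumours (red), by the probe set with the highest mean; points are arrays with a marker per replicate, and dashes with bars are means ± SD. For Gbp7 this is not the probe set past the threshold, but the other one (1.18 log2, limma adjusted p = 0.158). Alb/AEG-1 values lie above all wild-type values for 8 of the genes, and those of Mtdh overlap. The 8 genes were named for their small p, so their separation is no independent result.

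Markers of liver tumours and fetal liver formed the list with the largest mean difference. Scd2, a desaturase abundant in fetal tissues, was at 5.35 ± 0.51 (SD, n = 3) in wild-type and 8.72 ± 0.55 in Alb/AEG-1 tumours by its probe set with the highest mean. Tspan8 was at 3.49 ± 0.04 and 8.39 ± 1.44. Afp, the fetal serum protein alpha-fetoprotein and a clinical marker of hepatocellular carcinoma, was at 5.25 ± 0.30 and 8.24 ± 1.16 (difference 2.99 ± 0.51 log2, adjusted p = 0.467), and 4 of its 5 probe sets differed upwards, by up to 4.92. Tff3, a secreted trefoil peptide, differed by 3.14 ± 0.55 and Lcn2, the iron-siderophore-binding lipocalin 2, by 2.33 ± 0.46. Golm1, a Golgi membrane protein shed into serum, differed by 1.17 ± 0.28, Prom1, a progenitor cell surface marker, by 1.54 ± 0.47, and Ly6d by 1.54 ± 0.49.

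Of the 21 measured members, 0 passed when adjusted over all probe sets and 9 when adjusted over the list alone. These 9 were the 8 genes above, upwards, and Cpe, a carboxypeptidase, downwards (-0.81 ± 0.17). The Cpe value comes from a probe set that may bind related transcripts, and a more specific one differed by 2.69 ± 1.02. The list rose with a mean difference of 1.06 log2 and a median of 0.37 (adjusted p = 9.17e-06 with limma's camera and a preset correlation of 0.01; adjusted p = 0.688 with an estimated correlation). It was 1.21 higher in Alb/AEG-1 tumours within the lower animal numbers and 0.85 within the higher. Gpc3, another hepatocellular carcinoma marker, differed by 0.69 ± 0.53 and overlapped between groups.

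The list of lipid uptake and lipid droplet genes passed upwards, with 12 of 19 members positive and 7 negative, and the list for making fatty acids did not pass. Lpl, the lipase that frees fatty acids from circulating triglycerides, was at 7.34 ± 0.32 (SD, n = 3) and 9.53 ± 0.95, 4.58-fold higher (SE 0.43 log2). Apoa4 was at 10.08 ± 0.35 and 11.60 ± 0.37, the fatty acid transporter gene Cd36 differed by 0.80 ± 0.21 and the lipid chaperone gene Fabp4 by 0.43 ± 0.11. Mttp, whose product loads lipid onto secreted lipoproteins, differed by -0.49 ± 0.14. Of the 19 members, 0 passed when adjusted over all probe sets and these 5 when adjusted over the list alone, 4 upwards and Mttp downwards. In limma with the animal number range as a term, Mttp did not pass over the list alone (-0.42, adjusted p = 0.0664). The list rose by a mean of 0.43 log2 (adjusted p = 0.00656; adjusted p = 0.669 with an estimated correlation), 0.52 within the lower and 0.25 within the higher animal numbers, and missed the threshold without Alb/AEG-1 replicate 1 (adjusted p = 0.0636).

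In the list of de novo lipogenesis the mean difference was -0.02 while the median was 0.05 and the test pointed upwards (adjusted p = 0.857), with 0 of 21 members past the threshold in either adjustment. Srebf1, encoding a transcription factor for lipogenic enzymes, differed by 0.52 ± 0.18 (0.31 without wild-type replicate 3) and Mlxipl, encoding a glucose-responsive one, by -0.24 ± 0.11. The difference of this list turned with the animal number, at -0.39 within the lower and 0.49 within the higher numbers, and without Alb/AEG-1 replicate 3 it was called lower (mean -0.24, adjusted p = 0.0161). The remaining Alb/AEG-1 arrays all lie in the lower numbers, so that call cannot be told apart from the range. Among genes of fatty acid oxidation and targets of PPAR alpha, Vnn1, a pantetheinase, differed by 1.22 ± 0.22 and was the 1 of 23 that passed when adjusted over the list alone. Fgf21, a hepatic hormone, differed by 0.77 ± 0.19 and Ppara itself by -0.56 ± 0.16. That list did not pass (mean -0.03, adjusted p = 0.298), nor did cholesterol synthesis (mean 0.13, adjusted p = 0.339). The cholesterol list also turned with the animal number, at -0.42 within the lower and 0.45 within the higher numbers, and without wild-type replicate 1 it was called higher (0.40, adjusted p = 6.70e-07). The remaining wild-type arrays all lie in the higher numbers, so this call cannot be told apart from the range either.

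Interferon-stimulated genes and macrophage markers passed as lists, with few or no single members past the threshold. Among 23 interferon-stimulated genes, 21 had a positive difference. The chemokine gene Cxcl9 differed by 0.69 ± 0.20 log2 (SE, n = 3 per group), Oas1a, a sensor of double-stranded RNA, by 0.60 ± 0.17, the transcription factor gene Irf7 by 0.42 ± 0.11 and Gbp3 by 0.39 ± 0.10. These 4 passed when adjusted over the list alone (each adjusted p = 0.0498) and 0 when adjusted over all probe sets. Their unadjusted limma p lay between 0.0048 and 0.0087 in the plain fit. With the animal number range as a term it lay between 0.0060 and 0.019, so these calls lie at the threshold. The list rose by a mean of 0.30 (adjusted p = 1.95e-07; adjusted p = 0.669 with an estimated correlation), 0.19 within the lower and 0.42 within the higher animal numbers.

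Of 27 macrophage and Kupffer cell markers, 25 had a positive difference. Mpeg1, encoding the pore-forming perforin 2, differed by 0.90 ± 0.25, the complement subunit gene C1qb by 0.76 ± 0.21, the actin-binding gene Aif1 by 0.55 ± 0.15 (a probe set that may bind related transcripts) and Cd5l, a protein secreted by macrophages, by 0.54 ± 0.17. In either adjustment 0 members passed. The list rose by a mean of 0.33 (adjusted p = 1.95e-07; adjusted p = 0.688 with an estimated correlation). The means per array were 6.60, 6.25 and 6.44 in wild-type and 6.50, 6.80 and 6.98 in Alb/AEG-1 tumours, which overlap. The difference was 0.05 within the lower animal numbers and 0.63 within the higher.

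Markers of T and NK cells fell by a mean of 0.11 (adjusted p = 0.0106; adjusted p = 0.776 with an estimated correlation), with 23 of 25 members negative and 0 past the threshold in either adjustment. Most of these probe sets were dim, such as Cd5 at 4.05 and 3.68 (-0.37 ± 0.10) and the granzyme gene Gzmb at 3.79 and 3.50 (-0.29 ± 0.12). With dim genes left out, too few members remained for the list to be tested. The call was lost with the animal number range as a term (-0.09, adjusted p = 0.0633), after quantile normalization (adjusted p = 0.0748), without wild-type replicate 2 (adjusted p = 0.0693) and without Alb/AEG-1 replicate 1 (-0.06, adjusted p = 0.217). The list of MHC class II genes did not pass (mean 0.16, adjusted p = 0.119). Its invariant chain gene Cd74 differed by 0.51 ± 0.13 and was the 1 of 8 past the threshold when adjusted over the list alone. That call was lost in limma with the animal number range as a term (0.51, adjusted p = 0.0764 over the list alone). Cd74 differed by 0.23 within the lower and 0.78 within the higher numbers.

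Several further inflammatory lists did not pass. The complement list had a mean of 0.13 (adjusted p = 0.104) and the acute phase list 0.19 (adjusted p = 0.193). In the latter, Lcn2 passed upwards and Saa4, a constitutive serum amyloid, downwards (-0.41 ± 0.10) when adjusted over the list alone, while the inducible Saa1 differed by 1.10 ± 0.33 (0.70 without Alb/AEG-1 replicate 2) and did not pass. For targets of NF-kappaB, a factor that AEG-1 is reported to activate, the mean was 0.07 and the median -0.03 (adjusted p = 0.712). The neutrophil chemokine gene Cxcl1 differed by 1.17 ± 0.46, by 0.62 without wild-type replicate 3, and by 0.23 within the lower and 1.96 within the higher animal numbers.

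Proliferation genes and endoplasmic reticulum stress genes also passed as lists, without single members passing. Of 35 proliferation genes 29 had a positive difference. The list was dim, with a mean level of 4.87 in wild-type and 5.09 in Alb/AEG-1 tumours against 5.83 for the median probe set. Ccna2, a cyclin of S phase, differed by 0.44 ± 0.11 log2, the replication helicase gene Mcm6 by 0.51 ± 0.14, Ccnd1, the cyclin of G1, by 0.46 ± 0.13 and Mki67, which encodes the Ki-67 antigen, by 0.56 ± 0.23. The list rose by a mean of 0.21 (adjusted p = 2.08e-06; adjusted p = 0.688 with an estimated correlation), 0.23 within the lower and 0.17 within the higher animal numbers. Alb/AEG-1 replicate 2 carried the most of it, and without that array the mean was 0.12 (adjusted p = 0.00137). With dim genes left out the list passed narrowly (mean 0.22, camera adjusted p = 0.046).

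For endoplasmic reticulum stress and the integrated stress response, 18 of 24 members were positive and 0 passed in either adjustment. Asns, encoding asparagine synthetase, differed by 0.89 ± 0.26, the serine synthesis gene Psat1 by 0.62 ± 0.25 (0.31 without Alb/AEG-1 replicate 2) and the protein disulfide isomerase gene Pdia6 by 0.55 ± 0.17. The list rose by a mean of 0.22 (adjusted p = 0.0266; adjusted p = 0.75 with an estimated correlation). It was 0.38 within the lower and -0.05 within the higher animal numbers. The call was lost without wild-type replicate 1 (adjusted p = 0.172), without Alb/AEG-1 replicate 1 (mean 0.09, adjusted p = 0.25) and with dim genes left out (adjusted p = 0.145). Without Alb/AEG-1 replicate 3 the mean rose to 0.34 (camera, adjusted p = 8.99e-05), but the remaining Alb/AEG-1 arrays then lie only in the lower numbers. Targets of p53 (mean 0.14, adjusted p = 0.0932) and apoptosis regulators (mean 0.08, adjusted p = 0.151) did not pass.

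**Figure D2:**
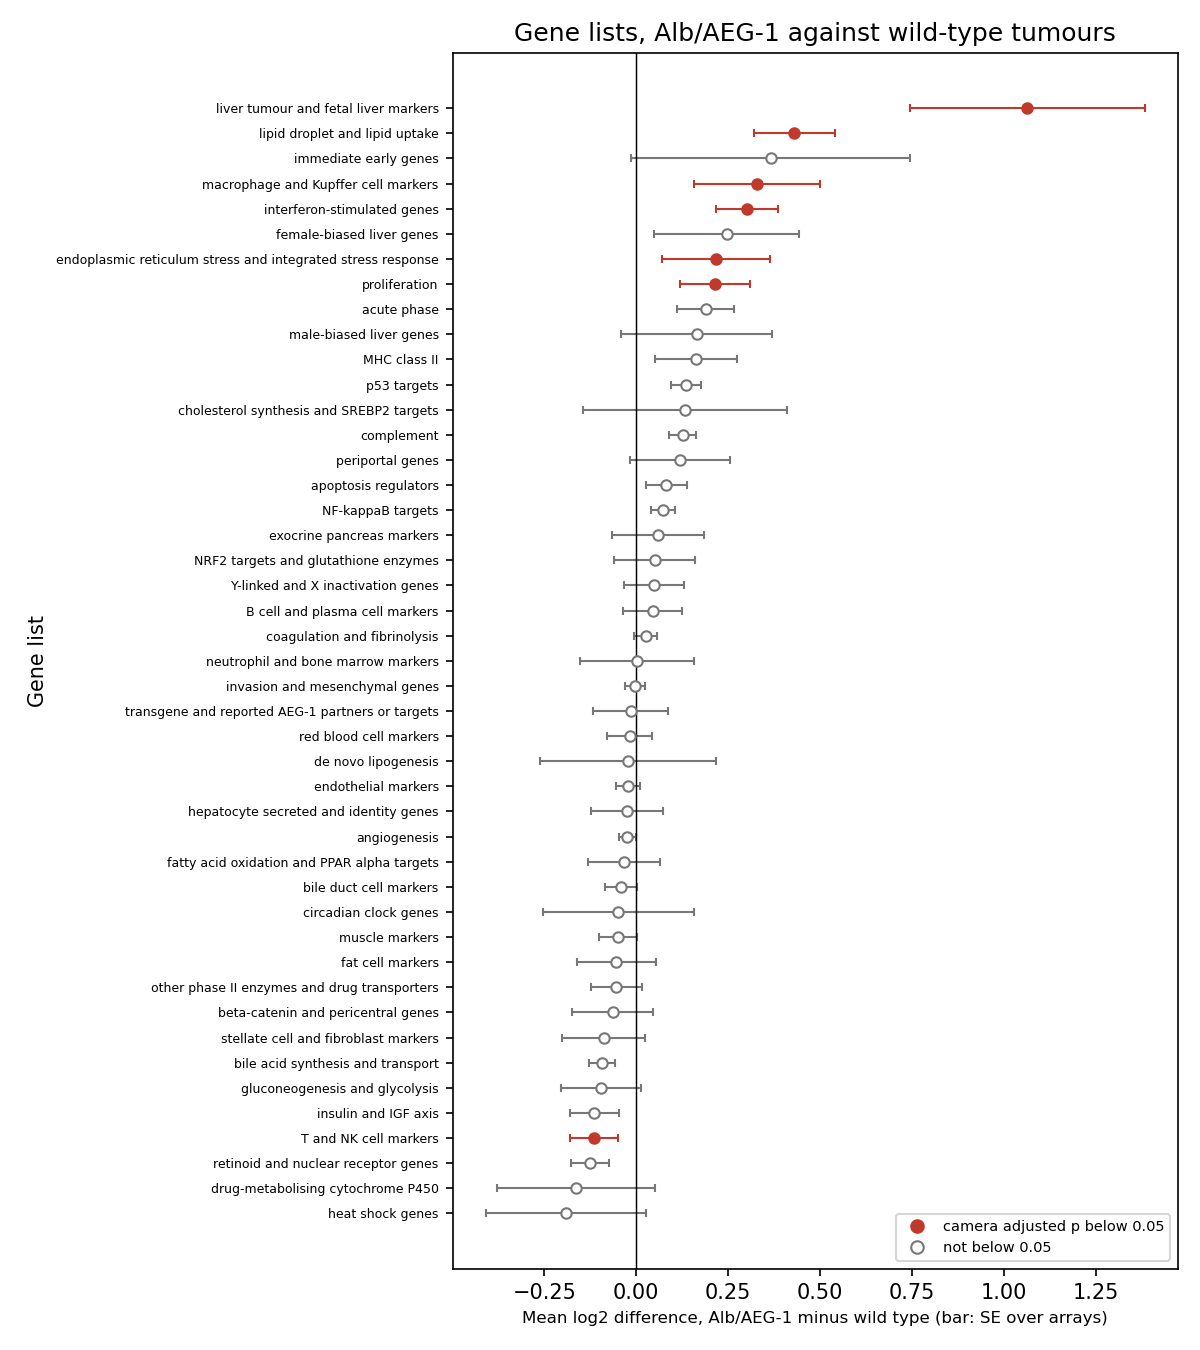
Mean log2 difference (x axis, Alb/AEG-1 minus wild type) of each of 45 gene lists (y axis); points are means over list members, bars the SE over arrays, and filled red points the 7 lists with a camera adjusted p below 0.05. The list of liver tumour and fetal liver markers lies farthest right, at 1.06, and the T and NK cell list is the 1 called list below 0, at -0.11.

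The lists of invasion and mesenchymal genes, of angiogenesis and of coagulation did not differ past the threshold. Their means were -0.003 (adjusted p = 0.51), -0.02 (adjusted p = 0.78) and 0.03 (adjusted p = 0.613). Anxa2 was the 1 of 29 invasion genes past the threshold when adjusted over the list alone. The adhesion receptor gene Cd44 differed by 0.54 ± 0.18 and the matrix metalloproteinase gene Mmp2 by -0.32 ± 0.11. For Cd44 and for Mmp2, 1 of 2 probe sets differed in the direction given. In the angiogenesis list Esm1, secreted by endothelial cells, differed by 0.41 ± 0.10 and the receptor gene Tie1 by -0.23 ± 0.11. The insulin and IGF list had 19 of 22 members negative (mean -0.11, adjusted p = 0.0993), among them the binding protein gene Igfbp2 at -0.62 ± 0.15.

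Hepatocyte functions showed no list past the threshold. Hepatocyte secreted and identity genes had a mean of -0.02 while the test pointed upwards (adjusted p = 0.743), periportal genes a mean of 0.12 with a test that pointed down (adjusted p = 0.897), and beta-catenin and pericentral genes -0.06 (adjusted p = 0.376). Hsd17b13, an enzyme of lipid droplets listed as periportal, differed by 2.28 ± 0.69, with a wild-type SD of 1.57. Bile acid genes had 16 of 19 members negative (mean -0.09, adjusted p = 0.0993). Drug-metabolising cytochrome P450 genes had 21 of 26 negative (mean -0.16, adjusted p = 0.0796). The mean difference of that list was only -0.06 within the lower and -0.001 within the higher animal numbers. With the number range as a term the list did not pass (camera, adjusted p = 0.321). The largest single differences were in part shared with the animal number. Cyp2c37 differed by -0.86 ± 0.45 in the plain fit and by -0.46 with the number range as a term, and Cyp2c54 by -0.84 ± 0.41 and -0.46 (-0.51 without Alb/AEG-1 replicate 1 and -1.32 without Alb/AEG-1 replicate 3). Other phase II enzymes and transporters (mean -0.05, adjusted p = 0.362), NRF2 targets (0.05, adjusted p = 0.324), gluconeogenesis and glycolysis (-0.10, adjusted p = 0.857) and retinoid and nuclear receptor genes (-0.13, adjusted p = 0.324) did not pass.

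Sex-biased, stress-responsive and clock genes were tested as well. Male-biased liver genes had a mean of 0.16 and a median of -0.02 (adjusted p = 0.897), and female-biased genes a mean of 0.25 (adjusted p = 0.376) that passed with the animal number range as a term (0.35, adjusted p = 0.04; adjusted p = 0.81 with an estimated correlation). Lpl was the 1 of 17 female-biased genes past the threshold when adjusted over the list alone. Immediate early genes had a mean of 0.37 (adjusted p = 0.342) and likewise passed with the range as a term (0.55, adjusted p = 0.0223; adjusted p = 0.81 with an estimated correlation). Egr1, a transcription factor induced within minutes of stimulation, differed by 1.90 ± 0.65. Heat shock genes had 14 of 16 members negative (mean -0.19, adjusted p = 0.0993), with the inducible chaperone gene Hspa1b at -0.89 ± 0.45 (-0.44 without wild-type replicate 3 and -0.54 without Alb/AEG-1 replicate 2). Circadian clock genes had a mean of -0.05 (adjusted p = 0.734).

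Markers of other cell types were measured beside these lists. Endothelial markers had a mean difference of -0.02 (adjusted p = 0.474), stellate cell and fibroblast markers -0.09 (adjusted p = 0.15), bile duct markers -0.04 (adjusted p = 0.613), B and plasma cell markers 0.04 (adjusted p = 0.899), red blood cell markers -0.02 (adjusted p = 0.549) and fat cell markers -0.05 (adjusted p = 0.702). Muscle markers were at -0.05 (adjusted p = 0.376), Y-linked and X inactivation genes at 0.05 (adjusted p = 0.497), and neutrophil and bone marrow markers at 0.002 while their test pointed down (adjusted p = 0.362). Exocrine pancreas markers were at 0.06 (adjusted p = 0.376) and passed with the animal number range as a term (0.13, adjusted p = 0.04; adjusted p = 0.81 with an estimated correlation). Their means per array were 4.927, 4.992 and 4.959 in wild-type and 4.855, 4.939 and 5.261 in Alb/AEG-1 tumours. That call therefore rests largely on Alb/AEG-1 replicate 3, the only Alb/AEG-1 array in the higher numbers. Some of the lists that did not pass were called at the preset correlation with 1 array left out. Cytochrome P450 genes were called lower without wild-type replicate 1 (adjusted p = 0.0241) or Alb/AEG-1 replicate 3 (adjusted p = 2.41e-04), heat shock genes without wild-type replicate 2 (adjusted p = 0.00118) or Alb/AEG-1 replicate 3 (adjusted p = 0.00826), and stellate cell markers without wild-type replicate 2 (-0.19, adjusted p = 5.00e-04). Pericentral genes (-0.15) and fatty acid oxidation genes (-0.11) were called lower and complement genes (0.16) higher without Alb/AEG-1 replicate 3. Without wild-type replicate 1 or Alb/AEG-1 replicate 3, 1 genotype lies wholly in 1 animal number range. Calls in those fits cannot be told apart from a difference between the ranges. Immediate early genes were called higher without wild-type replicate 2 (0.59) or Alb/AEG-1 replicate 2 (0.66), MHC class II genes without Alb/AEG-1 replicate 2 (0.24) and p53 targets without wild-type replicate 3 (0.16).

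As a sign of RNA quality, the difference between the 3' and 5' probe sets of beta-actin was 1.20, 1.28 and 1.25 log2 in wild-type and 1.22, 1.22 and 1.10 in Alb/AEG-1 tumours.

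The arrays also differed by animal number range, clock genes among them. With genotype as a term, 1 probe set passed between the higher and the lower numbers, and 331 had an unadjusted p below 0.05 with at least a 1.5-fold difference. The passing probe set belonged to Usp2, a deubiquitinase gene with a daily rhythm in liver. The Usp2 probe set with the highest mean differed by 1.40 ± 0.13 log2 (higher minus lower, adjusted p = 0.0821). Npas2, a partner of the clock transcription factors, was at 6.14 ± 0.33 (SD, n = 3) in the lower and 3.75 ± 0.31 in the higher numbers, a difference of -2.46 ± 0.21 (adjusted p = 0.0821). The rhythmic genes Per2 (1.48 ± 0.27), Tef (1.28 ± 0.22) and Nfil3 (-0.92 ± 0.19) did not pass over all probe sets. Some clock genes were mixed within the higher numbers. Wild-type replicate 3 had Dbp at 6.59, near the lower-numbered mean of 6.90 ± 0.93 (SD). Wild-type replicate 2 and Alb/AEG-1 replicate 3 had Dbp at 10.17 and 9.62. Clock, at 7.62 in wild-type replicate 3, also lay near its lower-numbered mean of 7.63. As a list the clock genes did not pass camera, which tests for a shared direction (adjusted p = 0.0569), while 10 other lists did, led by cytochrome P450 genes. With an estimated correlation these 10 lists did not pass (camera, adjusted p between 0.642 and 0.831). By limma's fry for members moving either way the clock list had an adjusted p of 0.0149, and other lists had lower ones, such as bile acid genes at 3.52e-04. As each range holds both genotypes, the differences between genotypes above are given within each range or with the range as a term where that changed the call of a list or a call over all probe sets. Calls of members adjusted over the list alone could change too, as for Cd74 and Mttp, and are not all given that way.

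**Figure D3:**
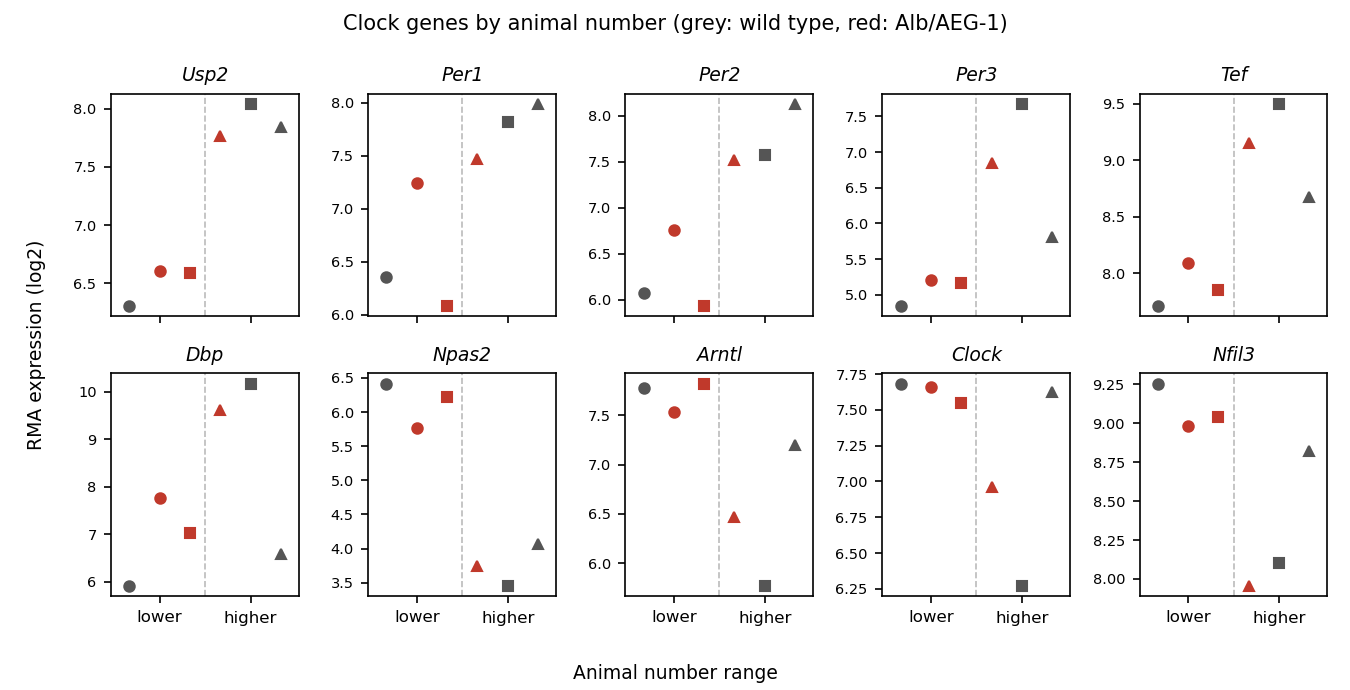
Expression (RMA log2, y axes, scaled per panel) of 10 clock genes on the 6 arrays, in order of animal number from left to right; the dashed line parts the lower range of numbers from the higher, with wild type in grey, Alb/AEG-1 in red and a marker per replicate. Usp2 lies between 6.31 and 6.60 on the lower-numbered arrays and between 7.77 and 8.04 on the higher-numbered, and Npas2 is higher on all 3 lower-numbered arrays.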

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

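The settings were chosen before the data were examined, apart from the animal number range with an estimated correlation, which was added after the results were seen. Over 16 alternative fits, 2925 of 2933 values of named genes kept their direction and side of the threshold, 2 were stronger and 6 reversed. None of the probe sets standing for these genes passed in the plain fit, so staying on that side was nearly fixed in advance. The size of single differences moved more. That of Hmgcs1 was 0.26 without wild-type replicate 3 and 1.36 without wild-type replicate 1. Of 118 values of the 7 called lists, 89 stayed called and 29 were not, with no reversal; of 757 values of all lists, 700 stayed, 29 were weaker, 27 stronger and 1 reversed. The count of probe sets past the threshold was 1 in the plain fit. It was 2 with trend moderation (1 of them lower), 2 with the mean of all probe sets per gene (2 higher, Gbp7 at 1.46 and Scd2 at 1.65, adjusted p = 0.0255), 0 with 1 probe set per gene (0 higher) and 0 with the animal number range as a term (0 higher). With 1 array left out it was 0 or 1, with 0 or 1 higher and 0 or 1 lower, and none of these was the Gbp7 probe set. A Cpe probe set was called higher without Alb/AEG-1 replicate 1 and an Afp probe set higher without Alb/AEG-1 replicate 2. A probe set with no gene symbol was called lower without wild-type replicate 3. The count at an unadjusted p below 0.05 and 1.5-fold was 183 in the plain fit, 113 with dim probe sets left out, 114 with 1 probe set per gene, 94 with their mean, and 150 to 361 with 1 array left out. The fits with fewer probe sets had fewer to count, and the cause of the other changes was not tested. The number of called lists was 7 in the plain fit, 12 with dim probe sets left out, 4 to 13 with 1 array left out, 0 with an estimated correlation, 0 by fry and 0 with the range as a term and an estimated correlation. Reversed values were those of Cpe (2.69 with cross-binding probe sets left out, 0.94 with the mean of probe sets), Tnni2 (0.0278 with cross-binding probe sets left out), F12 (-0.18 without wild-type replicate 3, 0.44 without wild-type replicate 2), Uty (-0.0145 without Alb/AEG-1 replicate 2, 0.138 without replicate 3), Cpa1 (-0.0364 without Alb/AEG-1 replicate 3, 0.26 without replicate 1) and the de novo lipogenesis list. The test of that list pointed upwards in the plain fit, at a mean of -0.02, and downwards without Alb/AEG-1 replicate 3 (mean -0.24, adjusted p = 0.0161), and its mean was 0.0949 without Alb/AEG-1 replicate 1. For Cpe and Tnni2 another probe set stands for the gene, and for the others the cause was not tested. No paired analysis was possible because the groups share no animal number. The median probe set lay at 5.83 log2, and differences of dim probe sets are limited by background.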

Other observations

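Drug metabolism was among the gene groups that passed as lists between the higher and the lower animal numbers, with genotype as a term. These lists were looked at for this contrast after the clock genes had been seen. Nr1i3, encoding the xenobiotic receptor CAR, was at 7.83 ± 0.11 (SD, n = 3) in the lower and 9.06 ± 0.16 in the higher numbers, a difference of 1.22 ± 0.12 log2 (SE, adjusted p = 0.0839). Its known target Cyp2b10 (1.62 ± 0.38) and the hepatic cytochromes Cyp2b9 (2.45 ± 0.70), Cyp2c37 (1.21 ± 0.19), Cyp2c54 (1.12 ± 0.17), Cyp2c50 (0.88 ± 0.15) and Cyp2b13 (0.83 ± 0.12) passed when adjusted over the list alone, 6 of 26, and 0 genes of the list passed over all probe sets. Cyp2b9 and Cyp2b13 were also members of the female-biased list. The cytochrome P450 list rose by a mean of 0.40 (limma's camera, adjusted p = 1.06e-05; adjusted p = 0.642 with an estimated correlation). Phase II enzymes and transporters rose by 0.14 (adjusted p = 0.00446; adjusted p = 0.642 with an estimated correlation), with the sulfotransferase gene Sult1d1 at 0.83 ± 0.15 and the efflux pump gene Abcb1a at 0.75 ± 0.14.

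Cholesterol synthesis genes fell by a mean of 0.35, with 17 of 18 negative (adjusted p = 1.91e-04; adjusted p = 0.736 with an estimated correlation). No single member passed over the list alone (0 of 18), with the sterol demethylase gene Cyp51 at -0.59 ± 0.16. Male-biased genes fell by a mean of 0.39 (adjusted p = 0.00729; adjusted p = 0.642 with an estimated correlation), among them the fatty acid elongase gene Elovl3 at -2.43 ± 0.50 and the steroid dehydrogenase gene Hsd3b5 at -0.70 ± 0.10. The direction was not shared by all 16 male-biased genes, with 10 negative and 6 positive. Immediate early genes rose by 0.55 (adjusted p = 9.09e-04; adjusted p = 0.642 with an estimated correlation), with the phosphatase gene Dusp1 at 1.71 ± 0.43 and the transcription factor gene Jun at 1.93 ± 0.60 and 0 of 21 members past the threshold over the list alone. Pericentral genes rose by 0.18 (adjusted p = 9.09e-04; adjusted p = 0.642 with an estimated correlation), with the ammonium transporter gene Rhbg at 0.66 ± 0.13. Exocrine pancreas, fat cell, heat shock and fatty acid oxidation lists also passed, with means of 0.21, 0.19, 0.20 and 0.13 and 0 members past the threshold. With an estimated correlation they did not (adjusted p = 0.642, 0.642, 0.831 and 0.736). The exocrine pancreas rise was largely that of 1 array, Alb/AEG-1 replicate 3 (list mean 5.261, against 4.855 to 4.992 on the other arrays). Wee1, a cell cycle kinase gene driven by the clock, differed by 1.18 ± 0.12 and Serpina12, encoding vaspin, by -1.64 ± 0.18 (adjusted p = 0.0928).

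The clock difference between the animal numbers was weighed after it was seen, and only the prediction for the spiked-in controls was written before its value. Scoring genes that peak in the evening upwards and those that peak in the morning downwards, without Usp2 and Npas2, the mean over 13 genes was 0.85 ± 0.23 log2 (SE over genes), at percentile 100 of 10000 random lists matched in expression, but the score was built after the clock genes had been seen and so is no independent test. Of the scored genes, 7 of 9 evening and 3 of 4 morning genes moved in the scored direction. The higher range was itself mixed for some clock genes, as for Dbp. Collection at another time of day could account for the clock difference and remains open, as the labels give no time. That score has genotype as a term, which takes out a shared genotype difference. Its SE over arrays was 0.38 and rests on few arrays, so whether unequal numbers of the genotypes contribute is not settled. The score was 0.91 within wild-type and 0.78 within Alb/AEG-1 tumours, each with a single array in 1 of the ranges. The spiked-in hybridization controls differed by -0.0315 (pooled SD 0.17, 18 probe sets), so no shift shared by these controls was seen. Their mean on quantile-normalized arrays cannot show an effect that moves probe sets both ways, so a difference in hybridization remains open.

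The tests of the tumour marker difference were chosen after the result was seen. With the animal number range as a term the mean was 1.03 log2 (SE 0.32 over members, 0.39 over arrays). It stayed close to the 1.06 of the plain fit, and the difference was positive within both ranges. List members are not independent and the SE over arrays rests on few arrays, so a contribution of the range is not excluded. More bile duct cells in the samples remain open: the 12 bile duct markers outside the list had a median of -0.11 (SD 0.26), but only 2 of them lay above the median probe set. A different share of non-tumour liver remains open too, since the hepatocyte genes (mean -0.0242) are common to tumour and liver. The biological explanation, the genotype, is the grouping itself and has no further test here.

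The tests of the macrophage difference were also chosen after the result was seen. A lower share of hepatocytes would raise all other cell types, but the median difference was -0.0349 (SD 0.17) over 22 endothelial markers and -0.0936 (SD 0.22) over 24 stellate cell markers, below the macrophage mean of 0.33 by more than those spreads, and 16 markers of each cell type lay above the median probe set. The animal number range remains open as a part of it, with a mean of 0.05 within the lower and 0.63 within the higher numbers. The genotype has no further test here.

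Splitting the 6 arrays into 3 and 3 in all 10 ways gave, for the count of probe sets past the threshold, 1 in the real split and 9 in the highest other, with 4 of 10 splits as large. For the count at an unadjusted p below 0.05 and 1.5-fold it gave 183 and 357, with 2 of 10 as large, and for called lists 7 and 12, with 8 of 10 as large. The split by animal number held the 9 and the 357. Single lists were also called in other splits: the unadjusted camera p of the tumour marker list was 8.15e-07 in the real split and 1.54e-08 in another, that of the macrophage list 8.65e-09 against 1.17e-09 and 1.12e-16 in 2 others, and that of the interferon list 8.28e-09 against a lowest other of 1.72e-08. The 10 splits can give no share below 0.1 for these counts or lists.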
